A study of Mus musculus with 2 samples.

How the data were processed

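The samples were 2 single-cell ATAC-seq libraries of sorted DCs from tumour-draining lymph nodes. Per the submitters' processing notes, the authors ran Cell Ranger ATAC 2.0.0 on mm10 for each library. The deposited values are raw counts of transposition events per peak and cell barcode, not divided by depth, with a separate peak list per library. Of the deposited entries, 87.0% and 87.2% were even numbers, as when both ends of a fragment are counted. Fragment files, sequence and a strand-aware annotation were not in hand.

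Peaks that overlapped by at least 1 bp were merged in Python, and the 135650 regions with a peak in both libraries were used. Overlaps between the peak lists and with genes were counted with bedtools 2.31.1. Peaks on unplaced scaffolds held 0.0971% and 0.0974% of counts, and chromosome Y held 22118 and 18615 counts. Both were left out of clustering, naming and tests, but not out of the number of regions or the counts per cell. Of 2694 and 2778 barcodes, those with at least 5000 counts were kept, 2553 and 2548. For each library 2 simulated doublets per cell were made, and the cells most like them were removed, at 0.8% per 1000 cells, 52 cells (2.04%) in each. The cells removed had median counts of 67423.5 and 56591. Gene windows spanned the gene body and 2 kb on both sides (RefSeq genes of mm10), since the table gave no strand, whereas the plan had been 2 kb upstream. Of 21627 protein-coding genes 16799 had a region. Windows of neighbouring genes overlap, and a shared region counted for each.

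Cells were clustered on 67293 regions of odd-numbered autosomes outside the windows of listed genes, so that no tested count formed a cluster. Counts were weighted by inverse region frequency, and 30 components were computed with the first left out, centred per library. A graph of 20 nearest neighbours was split by the Leiden method at resolution 0.8 (SciPy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2, Python 3.11.15). A cluster took a name when at least 40% and at least 3 of a list's markers were raised. Raised meant by log2 0.5 or more, over a pseudocount of 10 CPM. Its 10 leading genes could also not hold more markers of another class than of its own. Leading genes were ranked over all genes, and regions in the windows of markers were among the tested regions. The naming of clusters was therefore not independent of all tested counts. There were 14 marker lists, of 121 genes. The DC lists were cDC1, cDC2, mature DC, pDC and Langerhans cell. The others were monocyte/macrophage, T cell, B cell, NK/ILC, plasma cell, neutrophil, mast cell, stromal or endothelial, and melanocyte. The naming share was taken over all markers of a list rather than the detected ones, and the exact decomposition replaced a randomized one so that results repeat, and both choices were settled after the data were examined. Values with the randomized one are in the closing part. Median counts per cell were 39329 and 35814 in cDC1-like, 37625 and 33259 in cDC2-like, 36604.5 and 31708 in mature DC-like, and 33778 and 31577.5 in pDC-like cells.

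Counts were summed per class and library, giving 8 sums with library sizes from 2285691 to 8873099. edgeR 4.0.16 (R 4.3.3) fitted a quasi-likelihood model with class and library as terms, TMM scaling and filterByExpr, which left 3 residual degrees of freedom and a common biological coefficient of variation of 0.0462. Each DC-like class with at least 50 cells in both libraries was set against the mean of the other 3, and p was adjusted by Benjamini-Hochberg over 7497 genes, which lay on even-numbered autosomes and X or in the result lists, with naming markers left out. Regions of even-numbered autosomes and X were tested alike, 59223 in all. Values of single regions in named genes come from a separate fit, which added regions in the windows of listed genes on any chromosome. The threshold was an adjusted p of 0.05. Per-cell values were not tested as replicates. On simulated data with 200 changed genes the fit recovered 77% of genes changed by log2 0.5 and 91% of those changed by log2 1, with 4 false calls among 172. Genes were changed in mature DC-like cells alone, as many up as down. In the data 2990 to 4194 genes were called per class, so the simulation does not show the share of false calls at such numbers.

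The 15 result lists, of 281 genes, were fixed with the comparisons, tests, naming markers and most alternatives before the data were examined. They were sterol synthesis and uptake, sterol efflux and storage, fatty acid synthesis, glycolysis and lactate handling, immunoregulatory molecules, costimulation and cytokines, chemokines and chemokine receptors, NF-kB pathway, interferon-stimulated genes, MHC class I and MHC class II antigen presentation, pattern recognition, DC transcription factors and signalling, cytoskeleton and migration, and cell cycle. Pcsk9, Mx1 and Mx2 had too few counts to be tested. camera (limma 3.58.1) with a preset correlation of 0.01 tested 60 pairs of list and class, adjusted together, with an estimated correlation and with fry beside it. The genes named were, per class, the 8 largest rises and the 8 largest falls among genes called with the same sign in both libraries, 2 members per list with the smallest p, and 12 genes always given. Other members are examples of their list. Since counts come mostly in pairs, each cell's count per region was halved and rounded up as an estimate of fragments wherever a gene had 0 to 3 counts in a class, a choice made after the data were examined. For a gene with 0 counts in a class the fold is a floor from 3 fragments, and for 1 to 3 counts it is a ratio of fragments over library size with an exact 95% Poisson interval of the class's fragments.

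Alternatives were median-of-ratios scaling, no filter, no library term, DESeq2 1.42.0, counts within 1 kb of gene ends, halved counts, other Leiden resolutions, even-numbered autosomes for clustering, no centring, other doublet numbers, cells thinned to 5000 counts, 50% reciprocal overlap and each library left out. Chosen after the data were examined were a minimum of 10000 counts, the largest mature cluster alone, all myeloid clusters in the fit, and the randomized decomposition with 5 iterations. The planned motif test was not run, since no genome sequence was given. Figures were drawn with Matplotlib 3.10.9.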

Results

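Open chromatin was measured by single-cell ATAC-seq, in which a transposase inserts adapters into accessible DNA of single nuclei. The cells were dendritic cells (DCs) from the inguinal tumour-draining lymph node of mice with inducible melanoma, in which 4-hydroxytamoxifen on the back activates mutant Braf and deletes Pten in melanocytes. Nodes were taken 4 weeks after induction, and cells were sorted as lineage-negative, CD11c-positive and high in MHC class II. The series held 1 group of 2 libraries and no control node, so the comparisons were made between classes of cells within the libraries. The deposited counts summed to 90104646 in library 1 and 79723710 in library 2. After filtering, 2501 and 2496 cells remained, with a median of 34484 and 30877 counts and 13366 and 12400.5 open regions per cell. The labels do not say whether the libraries came from separate mice, so each p below rests only on these 2 libraries, whose spread may be technical. For genes, that spread is what remains after the library term, and the main fit pooled it over all genes (prior degrees of freedom infinite). The p and SE of a gene therefore do not reflect its own spread between the libraries. Intervals and floors cover counting error only, and any PCR copies among the counts would not be independent molecules. Accessibility is not expression, and no RNA value enters here.

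Library 1 had 155250 peaks with a median width of 878 bp, and library 2 had 157998 with a median width of 877 bp, covering 131.9 Mb and 134.2 Mb. Of these, 87.6% and 86.03% overlapped a peak of the other library by at least 1 bp, and these shared peaks held 98.3% of the counts in each. Within 1 kb of a gene end lay 13.0% and 12.8% of peaks, a further 47.2% and 47.0% lay inside genes, and 39.7% and 40.2% lay elsewhere. Across regions present in both libraries, log2 CPM (normalised counts as CPM, plus 1) had a Pearson correlation of 0.994 and a Spearman correlation of 0.986. These are correlations across regions, which are not independent replicates. The chi-square per degree of freedom was 2.57. Counting both ends of a fragment can by itself raise it from 1 to 2 at most, so 2.57 is more than such pairing gives. Whether PCR copies remain among the counts could not be checked without fragment files. The rest of the excess was therefore not divided between such copies and a difference between the libraries.

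cDC1-like cells, named by markers of the conventional DCs that cross-present antigen, made up, with 592 cells in library 1 and 635 in library 2, 23.7% (exact 95% interval 22.0 to 25.4) and 25.4% (23.7 to 27.2), the largest class at the setting used. cDC2-like cells, the conventional DCs that mainly present antigen to helper T cells, made up 12.8% (11.5 to 14.1) and 13.3% (12.0 to 14.7), with 319 and 333 cells. Mature DC-like cells, named by markers of migrated DCs such as Ccr7, Fscn1 and Ccl22, made up 7.60% (6.59 to 8.71) and 7.41% (6.42 to 8.51), with 190 and 185 cells. Plasmacytoid (pDC)-like cells made up 9.88% (8.73 to 11.1) and 9.38% (8.26 to 10.6), with 247 and 234 cells. Besides these 1348 and 1387 DC-like cells, monocyte/macrophage-like cells made up 8.24% and 7.93%. T cell-like cells made up 4.16% and 3.97%, B cell-like cells 3.16% and 2.97% and NK/ILC-like cells 1.80% and 2.04%. Unnamed clusters held 28.8% and 27.5% of cells. The largest of these, of 297 and 283 cells and of 206 and 179 cells, came closest to the cDC2 list, with 6 and 4 of 10 markers raised. Both stayed unnamed because their 10 leading genes held 1 marker of another class and none of the cDC2 list. That marker was Pdpn of stromal cells in the former and Tbc1d4 of mature DCs in the latter. The gate on lineage markers, CD11c and MHC class II sets which cells entered the libraries, and the plot of shares by class gives all 8 named classes. Other settings put the mature DC-like share at up to 9.58% and the cDC2-like share at up to 26.0%. The cDC2-like class was then the larger in both libraries without centring, and in library 1 at Leiden resolution 1.2 (24.1%) and with clustering on even-numbered autosomes (24.99%).

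**Figure D1:**
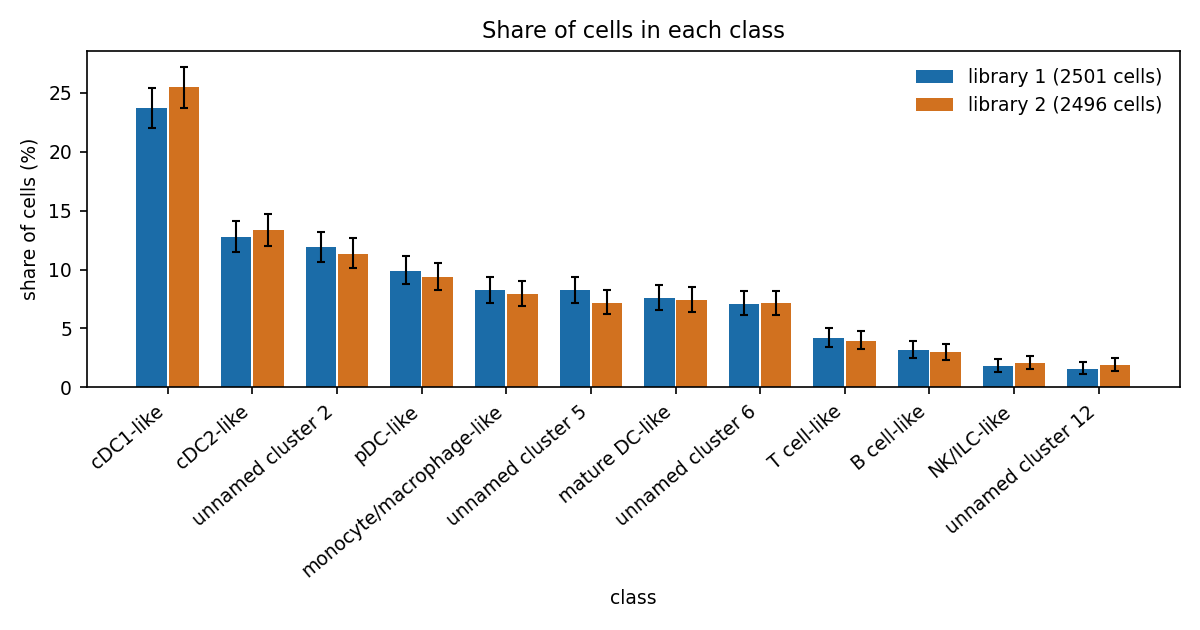
Share of cells (percent, y axis) in each named class for library 1 and library 2, with exact 95% binomial intervals as error bars. At the setting shown, the cDC1-like class held 23.7% and 25.4% of cells and the cDC2-like class 12.8% and 13.3%, and the mature DC-like class held 7.60% and 7.41%.

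The mean log2 fold of the cDC1 list was 1.0 in cDC1-like cells (7 of 10 markers raised), that of the cDC2 list 0.46 in cDC2-like cells (5 of 10, and 4 of 10 in both mature DC-like and pDC-like cells), that of the mature DC list 1.42 in mature DC-like cells (10 of 12) and that of the pDC list 0.97 in pDC-like cells (8 of 10). These markers named the classes, so they are not results. Of the lists of other cell types, the highest mean folds were 0.56 for plasma cells (3 of 6 raised) and 0.53 for T cells (4 of 9), both in pDC-like cells, and 0.57 for stromal or endothelial cells in cDC2-like cells (3 of 9), above the mean of the cDC2 list itself. The highest mean fold was 0.32 for Langerhans cells in mature DC-like cells, 0.24 for monocytes and macrophages and 0.11 for melanocytes in cDC2-like cells, 0.29 for mast cells and 0.21 for neutrophils in cDC1-like cells, and 0.11 for NK cells in pDC-like cells. For B cells it was 0.23, in pDC-like cells.

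The series title names a lactate-induced programme that depends on SREBF2, so the question for these data was which DC-like class had the more accessible sterol, immunoregulatory and lactate-handling genes. Each class was set against the mean of the other 3 DC-like classes (log2 fold change, n = 2 libraries per class). By this design the contrasts of a gene over the classes sum to 0, so a high level in one class lowers the values of the others. Rises in one class and falls in another are therefore not independent results, and a rise does not mean the highest level. In mature DC-like cells 12 of 25 tested genes of sterol synthesis and uptake rose, 3 fell and 10 did not pass. Ldlr, the receptor that takes up cholesterol-rich lipoprotein, rose by 0.71 (SE 0.063, adjusted p = 1.84e-27), at 293 ± 11.1 CPM (SD, n = 2) against 190 in the other classes. Hmgcr, which encodes the rate-limiting enzyme of cholesterol synthesis, rose by 0.25 (adjusted p = 4.58e-04), Sqle by 0.32 (7.67e-05), Hmgcs1 by 0.17 (0.0234), Cyp51 by 0.44, Pmvk by 0.55 and Sc5d by 0.48. The 3 that fell were Srebf2 itself, the transcription factor that activates sterol genes (390 ± 2.97 CPM against 501, log2 -0.36, SE 0.049, adjusted p = 9.43e-13), Scap (-0.40), which escorts it, and the reductase gene Tm7sf2 (-0.36). As a list these genes did not pass in mature DC-like cells (median log2 fold change 0.16, adjusted p = 0.275, and adjusted p = 0.562 with an estimated correlation). With counts near gene ends only, the calls of Srebf2 (-0.06) and Hmgcr (0.06) were lost, and with thinned cells or all myeloid clusters in the reference those of Hmgcr (0.21 and 0.13) and Hmgcs1 (0.081 and 0.077) were. Hmgcs1 was also lost at Leiden resolution 1.2 (0.14), without centring (0.14) and with DESeq2 (0.17), and it had 0.29 in library 1 and 0.038 in library 2.

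In cDC1-like cells the same list had 4 genes higher and 13 lower (median -0.16, adjusted p = 0.105) and passed with all myeloid clusters in the reference (-0.21). Mvd (-0.66, with 36.9% of its window counts shared with neighbouring genes) and Idi1 (-0.47), both of the mevalonate pathway, fell, while Srebf2 (0.17, adjusted p = 8.46e-05) and Hmgcs1 (0.26, adjusted p = 2.01e-05) rose. Srebf2 and Hmgcr (0.15) of this class changed sign near gene ends, to -0.05 and -0.08, and Hmgcs1 lost its call there (0.079) and with thinned cells (0.12). Hmgcr of this class was also lost in 5 further settings, at 0.050 to 0.16. Srebf2 had 0.07 in cDC2-like cells (adjusted p = 0.211, with 0.009 in library 1 and 0.128 in library 2), called with all myeloid clusters in the reference (0.15). In pDC-like cells it had 0.12 (adjusted p = 0.0148). cDC2-like cells had 3 genes higher and 3 lower (median 0.01, adjusted p = 0.941), with Ldlr at 0.62 (adjusted p = 1.55e-24) and Idi1 at 0.27. Idi1 had 0.39 in library 1 and 0.15 in library 2, and its call was lost with thinned cells at a fold of 0.28. pDC-like cells had 8 higher and 7 lower (median 0.03, adjusted p = 0.953), with Ldlr at -0.97 (adjusted p = 8.69e-41), Hmgcr at -0.31 and Mvd at 0.57. In pDC-like cells the calls of Srebf2 and Hmgcr were lost with thinned cells, at 0.19 and -0.28, and that of Hmgcr near gene ends, at -0.045. Sterol efflux and storage genes did not pass as a list in the 4 classes, with adjusted p of 0.0704 in cDC1-like, 0.354 in cDC2-like, 0.370 in mature DC-like and 0.107 in pDC-like cells, but in cDC1-like cells the list passed with thinned cells (median -0.08) and with all myeloid clusters in the reference (-0.07). The cholesterol exporter gene Abcg1 fell in mature DC-like cells (-0.84) and rose in pDC-like cells (1.14), and Npc1, needed to release cholesterol from lysosomes, had -0.49 and 1.05. In mature DC-like cells Npc1 had -0.26 in library 1 and -0.78 in library 2, and it changed sign near gene ends (0.18). Slc16a1, a lactate transporter gene, was not called in mature DC-like cells (-0.07, adjusted p = 0.660) but rose in cDC1-like (0.48) and cDC2-like cells (0.33) and fell in pDC-like cells (-0.73), with the call in cDC2-like cells lost when cells were thinned (0.21) and with all myeloid clusters in the reference (0.10). The differences between these contrasts were not themselves tested.

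**Figure D2:**
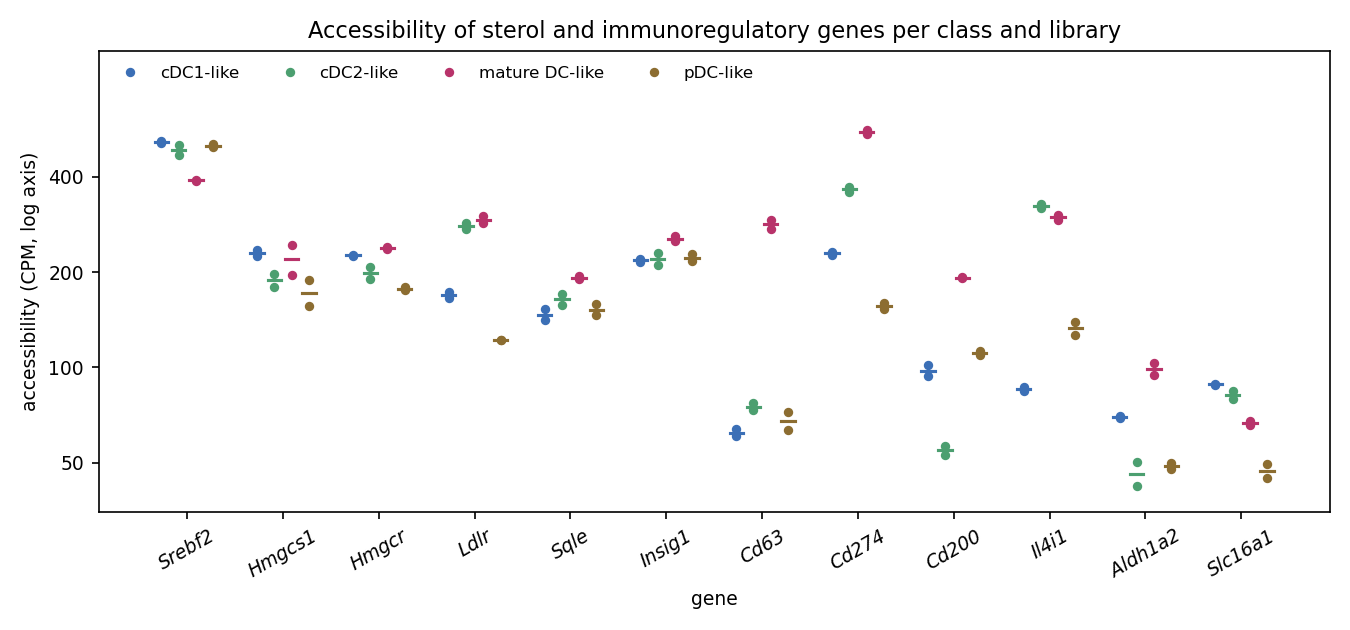
Accessibility (normalised CPM, log y axis) of the 12 genes given in each class, for both libraries (points) with the mean (line). Cd63 stands at 283 CPM in mature DC-like cells against 68.5 in the others, while Srebf2 stands lowest there at 390 CPM.

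The positions on mm10 were chromosome 15, 82147269 to 82205379 for Srebf2, chromosome 9, 21723576 to 21749919 for Ldlr, and chromosome 13, 96648962 to 96670936 for Hmgcr and 119690351 to 119708260 for Hmgcs1. Inside Ldlr, the region from 21727922 to 21728823 had 91.5 ± 7.90 CPM (SD, n = 2) in mature DC-like cells against 28.9 in the others (log2 1.90, adjusted p = 7.74e-14). Inside Srebf2 the region from 82167445 to 82168251 rose in mature DC-like cells (27.2 ± 3.22 CPM against 3.55, log2 2.94, adjusted p = 9.45e-10), while of 13 tested regions in the Srebf2 window 1 rose and 4 fell in this class. The Srebf2 region with the smallest adjusted p rose in each other class. It lay from 82196142 to 82197056 in cDC1-like cells (log2 2.09), from 82151819 to 82152669 in cDC2-like cells (2.01) and from 82186727 to 82187647 in pDC-like cells (2.39). Exons, introns and untranslated regions were not given.

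In mature DC-like cells 3643 of 7497 genes changed, 1832 higher and 1811 lower, 763 of them at least 2-fold, and 22006 of 59223 regions changed. The costimulatory and immunoregulatory lists rose together. All 17 tested genes of costimulation and cytokines rose (median 1.08, adjusted p = 5.73e-21, and adjusted p = 0.0736 with an estimated correlation), among them Cd40 (346 ± 11.5 CPM against 118, log2 1.73, adjusted p = 1.93e-135), Cd86 (1.08), Cd70 (3.57) and Tnfsf4 (2.71). Of 20 immunoregulatory genes 14 rose, 2 fell and 4 did not pass (median 0.79, adjusted p = 6.66e-13, and adjusted p = 0.0736 with an estimated correlation). Cd63, a tetraspanin gene, rose by 2.05 (SE 0.080, 283 ± 12.3 CPM against 68.5, adjusted p = 4.06e-142), and Fas, a death receptor gene, by 2.45 (212 ± 51.0 CPM against 38.8). Cd274, which encodes PD-L1, rose by 1.23 (SE 0.051, 553 ± 11.8 CPM against 251, adjusted p = 2.85e-126). Cd200 rose by 1.19, Il4i1 by 0.95 and the retinoic acid enzyme gene Aldh1a2 by 0.87, while Lgals9 (-0.52, with -0.32 in library 1 and -0.75 in library 2) and Tgfb1 (-0.23) fell. Il4i1 still stood higher in cDC2-like cells, at 328 and 319 CPM by library against 293 and 303 in mature DC-like cells. Of the window counts, 69.5% for Cd274, 26.4% for Cd63 and 100% for Il4i1 also lay in windows of neighbouring genes. With counts near gene ends only, Cd274 was no longer called (0.25).

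The NF-kB pathway list had 17 of 20 genes higher and none lower (median 0.68, adjusted p = 3.44e-16, and adjusted p = 0.0736 with an estimated correlation). Tnip1 (1.09) and Tnip3 (1.24), its members with the smallest p, and Nfkbia (0.82) encode proteins that restrain NF-kB. Of 15 chemokine and receptor genes 7 rose and 2 fell (adjusted p = 4.71e-04, and adjusted p = 0.162 with an estimated correlation), with Ccl17 at 2.08 and Cxcl9 at 3.63 against Ccr5 at -0.98. In the cytoskeleton and migration list 10 of 17 rose and 5 fell (adjusted p = 8.41e-03, and adjusted p = 0.223 with an estimated correlation), with Marcks at 0.95 and Anxa3 at 1.85 against Itgb7 at -0.66. Among DC transcription factors 15 of 26 rose and 7 fell (adjusted p = 0.0137, and adjusted p = 0.282 with an estimated correlation), with Stat4 at 1.63 and Etv6 at 0.77. Interferon-stimulated genes had 9 higher and 4 lower of 20 (adjusted p = 0.0366, and adjusted p = 0.285 with an estimated correlation). Stat1 (1.51) and Isg15 (1.15, with 100% of its window counts shared with neighbouring genes) rose, while Irf7 (-0.77) and Irf9 (-0.33), which drive such genes, fell. Of 13 MHC class II genes 9 fell and 4 rose (median -0.36, adjusted p = 0.0335, and adjusted p = 0.386 with an estimated correlation). H2-Ab1 (-0.84) and H2-Aa (-0.75) fell, while the transactivator gene Ciita (0.51) and the protease gene Ctss (0.39) rose.

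The remaining lists did not pass in mature DC-like cells. MHC class I had 9 higher and 2 lower of 16 (adjusted p = 0.190), pattern recognition 10 higher and 4 lower of 22 (0.150), and fatty acid synthesis 1 higher and 6 lower of 13 (0.156). Glycolysis and lactate handling had 5 higher and 4 lower of 26 (adjusted p = 0.812), with Pfkfb3 at 0.73 and Slc16a7 at -0.93, sterol efflux and storage 3 higher and 5 lower of 12, and cell cycle 3 higher and 4 lower of 16 (0.868). Adjusted over the list alone, the counts higher and lower were 14 and 3 for immunoregulatory genes, 4 and 5 for sterol efflux, 2 and 6 for fatty acid synthesis, 11 and 2 for MHC class I, 11 and 4 for pattern recognition, 15 and 8 for transcription factors, and unchanged for the rest. The interferon list was no longer called in 9 of 16 other settings (medians 0.062 to 0.25), the MHC class II list in 2 (-0.28 and -0.33), and the cytoskeleton list near gene ends (0.22). The transcription factor list turned there (camera direction down, median 0.066) and lost its call with the randomized decomposition (0.17), Pfkfb3 changed sign there (-0.10), and Stat1 lost its call there (0.21).

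**Figure D3:**
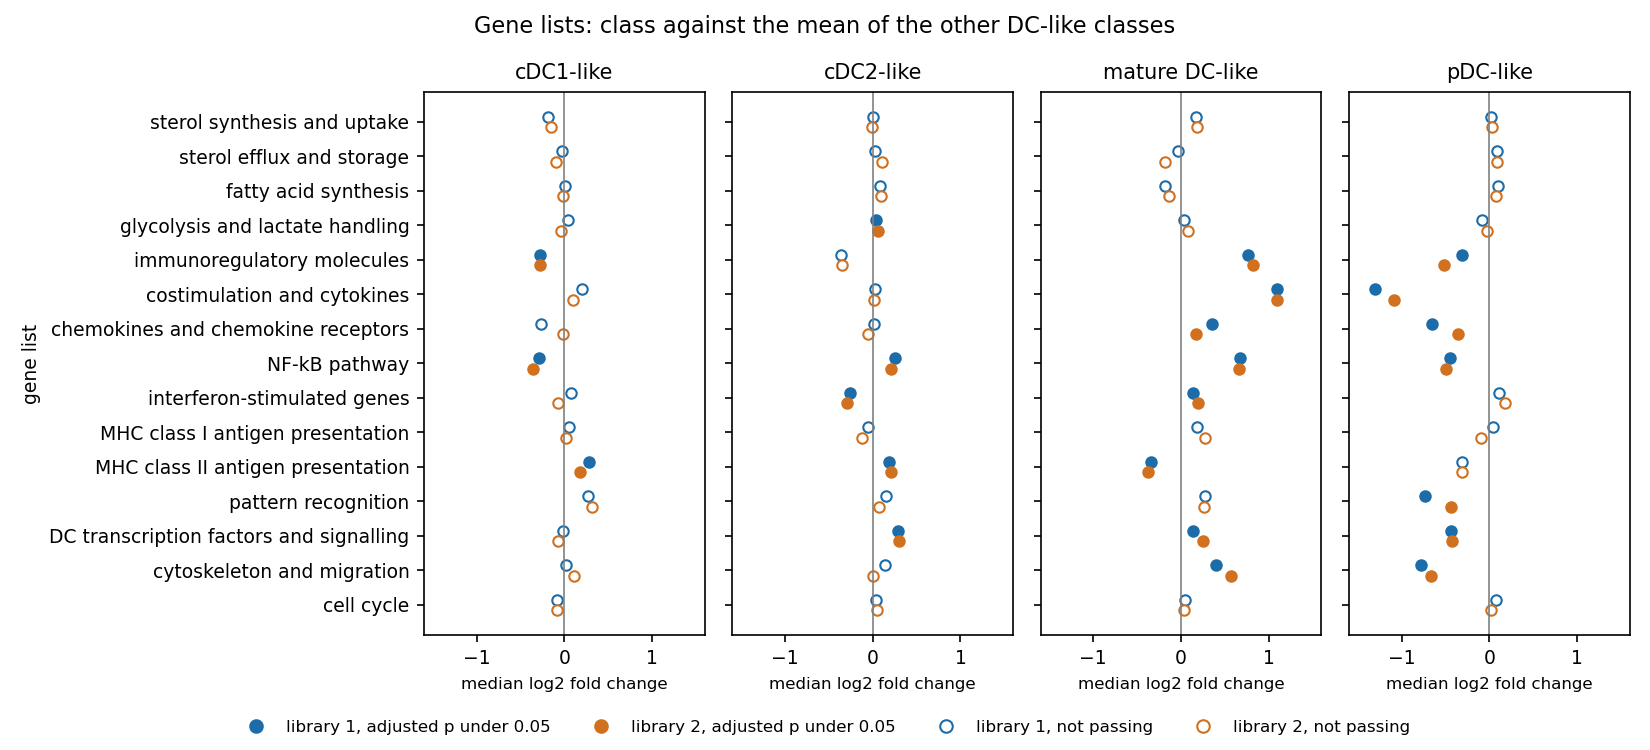
Median log2 fold change of each of the 15 lists (y axis) in each DC-like class against the mean of the other 3, per library (points), filled where the list's adjusted p is under 0.05. The costimulation list stands at 1.08 in mature DC-like and -1.21 in pDC-like cells, and the sterol synthesis list at 0.16 in mature DC-like cells without passing.

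Where a class in the reference had 0 counts, the fitted fold only ranks a gene, and CPM are given instead. The largest rises in mature DC-like cells were Lrit2 (46.0 CPM against 0.567), Cyyr1 (32.1 against 0.230) and Syt1 (17.4 against 0.110, with 4 counts in the others), followed by Nxph2, Olfr175, Slc13a4, Ces1a and Tnfrsf4. The libraries differed widely for Syt1, whose only region had 15.1 ± 7.51 CPM (SD, n = 2). Tnfrsf4, which encodes the T cell costimulatory receptor OX40, had 65.6 ± 0.747 CPM (SD, n = 2) against 1.06 (log2 6.46, with 6.06 and 5.58 by library, adjusted p = 2.98e-82), and 100% of its window counts also lay in windows of neighbouring genes. The region within 1 kb of its gene end on chromosome 4, from 156012022 to 156012969, had 56.7 CPM against 0.909 in the others. Inside Cd63, chromosome 10 from 128909001 to 128909965 had 156 ± 6.18 CPM against 11.6 (log2 3.85, adjusted p = 7.26e-21), and inside Cd274, chromosome 19 from 29363856 to 29364771 had 78.1 ± 6.07 CPM against 17.3 (log2 2.43, adjusted p = 1.01e-14). All 5 tested regions of the Cd63 window and all 10 of the Cd274 window rose. The 8 largest falls had 0 counts in mature DC-like cells. Defb28 was at least 21.9-fold lower, Rep15 at least 16.2-fold, Sox3 at least 5.55-fold, and Runx1t1, Nrxn3, Slc27a6, Pcdh8 and Trim63 at least 2.14-fold to 2.68-fold. Such a fall can rest on a high level in a single reference class. The only tested region of Defb28 had 66.8 CPM in pDC-like cells against a mean of 0.376 in the other classes. That of Nrxn3 was not called in mature DC-like cells (log2 -3.87). With all myeloid clusters in the reference, the falls of Rep15, Sox3, Defb28, Slc27a6 and Pcdh8 were no longer called, nor were those of Rep15 and Defb28 with thinned cells, Runx1t1 (-1.30) and Pcdh8 (-2.55) without doublet removal, Pcdh8 with the randomized decomposition (-2.53), or the rise of Olfr175 with DESeq2 (6.52).

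In cDC1-like cells 4108 genes changed, 2129 higher and 1979 lower, 727 of them at least 2-fold, and 29187 regions changed. Of the MHC class II list 9 of 13 rose and 2 fell (median 0.23, adjusted p = 0.0227, and adjusted p = 0.349 with an estimated correlation), with H2-DMb1 at 0.93 (83.1% of its window counts shared with neighbouring genes) and Marchf1, a ligase that removes class II from the surface, at 0.69. NF-kB genes fell, 15 of 20 against 3 that rose (median -0.31, adjusted p = 1.38e-04, and adjusted p = 0.141 with an estimated correlation), with Bcl3 at -0.93 and Ikbkb at -0.68. Immunoregulatory genes fell, 14 of 20 against 3 that rose (median -0.31, adjusted p = 0.0260, and adjusted p = 0.265 with an estimated correlation). Il4i1 (-1.46), Cd63 (-0.86) and Cd274 (-0.46) fell, whereas Havcr2 (0.87) and Ido1 (1.11) rose. Bcl3 (-0.0030) and Ikbkb (-0.089) lost their calls near gene ends, as did the immunoregulatory list (-0.21). With all myeloid clusters in the reference, the immunoregulatory (-0.25) and MHC class II (0.14) lists lost their calls.

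The other lists did not pass in cDC1-like cells. Costimulation and cytokines had 9 higher and 5 lower of 17 (adjusted p = 0.208), with Cd86 at 0.96 and Il12b at 1.19, and pattern recognition 12 higher and 4 lower of 22 (0.140), with Nlrp3 at 1.12 and Tlr11 at 1.56. Cytoskeleton and migration had 8 higher and 4 lower of 17 (adjusted p = 0.0705) and passed in 7 of 16 other settings, with a median from -0.01 to 0.13. MHC class I had 7 higher and 4 lower of 16 (0.569) with Wdfy4, needed for cross-presentation, at 1.29, and chemokines 6 higher and 6 lower of 15 (0.934) with Cxcl9 at 2.73. Transcription factors had 8 higher and 10 lower of 26 (adjusted p = 0.274), with Stat4 at -1.13 and Id2 at 0.65, and interferon-stimulated genes 4 higher and 8 lower of 20 (0.418). Fatty acid synthesis had 4 higher and 3 lower of 13 (adjusted p = 0.834), glycolysis 8 higher and 7 lower of 26 (0.861), sterol efflux 3 higher and 5 lower of 12, and cell cycle 2 higher and 6 lower of 16 (0.472). Adjusted over the list alone, the counts were 4 and 14 for immunoregulatory genes, 5 and 8 for interferon-stimulated genes, 7 and 5 for MHC class I, 8 and 11 for transcription factors, 3 and 6 for cell cycle, and unchanged for the rest. Of the largest rises, Gm34768 (17.9 CPM against 0.853) and Rnf165 (15.1 against 0.609) had the highest levels, and Fam25c, Tex11, Mcpt9, Ces2e, 6030498E09Rik and Fgf20 lay under 10 CPM. Pla2g4f (-3.84), Ifng (-3.75, with -2.09 and -3.43 by library) and Tenm3 (-3.42) fell. Of 6 tested regions in the Tenm3 window 0 were called in cDC1-like cells, while all 6 rose in pDC-like cells. In pDC-like cells the region with the smallest adjusted p had 77.6 CPM against a mean of 0.998 in the other classes. Lrit2 had 0 counts and was at least 48.5-fold lower, with 156 and 79 of the 250 counts elsewhere in mature DC-like cells. Gm14137 had 2 counts, taken as 1 fragment, and was 104-fold lower (18.6 to 4102), with 111 and 91 of the 212 counts elsewhere in pDC-like cells and a fitted log2 of -4.07. Gm14137 and Mcpt9 shared 100% of their window counts with neighbouring genes. Lrit2 and Gm14137 lost their calls with thinned cells (Gm14137 at -2.73) and with all myeloid clusters in the reference (-1.95), Lrit2 also with more doublets removed, and Mcpt9 (6.39) and Ces2e (6.30) with DESeq2.

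In cDC2-like cells 2990 genes changed, 1515 higher and 1475 lower, 374 of them at least 2-fold, and 16378 regions changed. Among DC transcription factors 17 of 26 rose and 2 fell (median 0.29, adjusted p = 8.20e-08, and adjusted p = 0.141 with an estimated correlation), with Rxra at 0.86 and Nr4a3 at 0.60 higher and Id2 at -0.77 lower. NF-kB genes rose, 14 of 20 against 4 that fell (median 0.22, adjusted p = 2.76e-05, and adjusted p = 0.141 with an estimated correlation), and the strongest, Tnip3 (1.15), encodes an inhibitor of the pathway. MHC class II genes rose, 7 of 13 against 2 that fell (adjusted p = 5.15e-03, and adjusted p = 0.282 with an estimated correlation), with H2-Eb1 at 0.44 and H2-Ab1 at 0.46. Glycolysis and lactate handling had 9 of 26 higher and 5 lower (median 0.04, adjusted p = 0.0335, and adjusted p = 0.265 with an estimated correlation), with Hk2 and the glucose transporter gene Slc2a1 both at 0.84. Interferon-stimulated genes fell, 12 of 20 against 5 that rose (median -0.35, adjusted p = 0.0420, and adjusted p = 0.285 with an estimated correlation), with Trim30a at -0.71 and Oasl1 at -0.75. The interferon list lost its call in 5 other settings (-0.33 to -0.11) and the glycolysis list in 4 (-0.049 to 0.057), and Slc2a1 lost its call near gene ends (0.032). The MHC class II list lost its call with all myeloid clusters in the reference (0.11).

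The remaining lists did not pass in cDC2-like cells. Immunoregulatory genes had 6 higher and 12 lower of 20 (adjusted p = 0.379), with Il4i1 at 1.11 and Cd274 at 0.43 against Cd200 at -1.22 and Ido1 at -1.16, and Cd274 changed sign near gene ends (-0.18). Costimulation had 7 higher and 5 lower of 17 (adjusted p = 0.812), chemokines 3 higher and 2 lower of 15 (0.658), pattern recognition 9 higher and 2 lower of 22 (0.104) with Tlr5 at 1.30 and Clec7a at 1.07, and MHC class I 2 higher and 4 lower of 16 (0.190). The pattern recognition list, with a median of 0.06, passed at Leiden resolution 1.2 (0.32), with clustering on even-numbered autosomes (0.27) and without centring (0.34). Fatty acid synthesis had 4 higher and 1 lower of 13 (adjusted p = 0.472), sterol efflux 4 higher and 1 lower of 12, cytoskeleton 6 higher and 7 lower of 17 (0.681), and cell cycle 3 higher and 0 lower of 16 (0.780). Adjusted over the list alone, the counts were 8 and 2 for MHC class II, 7 and 8 for cytoskeleton, and unchanged for the rest. The largest rises were Rp1l1 (40.6 CPM against 1.26, log2 5.28), Tmem210 (46.2 against 2.04, log2 4.54) and Rep15 (20.5 against 12.1, but 35.4 in pDC-like cells and 0 in mature DC-like cells), and then Aqp1, Pcdh15, Grin2a, A230072I06Rik and Podn. Chst9 fell (-3.83). Ntsr1, C8a, Ces1a and Agr3 had 0 counts and were at least 19.2, 8.20, 9.62 and 2.79-fold lower. The only tested region of Ces1a had 15.5 CPM in mature DC-like cells against a mean of 0.278 in the other classes. A region of Ntsr1 had 15.9 CPM in pDC-like cells against 0.232, so these falls rest mostly on a single reference class. With 1 to 3 counts, taken as 1 fragment each, Bpifb9a was 28.7-fold (5.14 to 1132), Tcaf2 22.9-fold (4.11 to 903) and Zfp612 19.7-fold lower (3.53 to 778). Tmem210, Rep15, C8a and Bpifb9a shared 100% of their window counts with neighbouring genes, and Podn 38.9%. Ntsr1, C8a, Ces1a and Bpifb9a (-1.75) lost their calls with all myeloid clusters in the reference, and Bpifb9a with DESeq2 (-4.49).

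In pDC-like cells 4194 genes changed, 2004 higher and 2190 lower, 1153 of them at least 2-fold, and 30482 regions changed. Genes of costimulation and cytokines fell, 15 of 17 against 1 that rose (median -1.21, adjusted p = 6.91e-11, and adjusted p = 0.0748 with an estimated correlation), with Cd86 at -2.23 and Cd83 at -1.64. NF-kB genes fell, 16 of 20 against 3 that rose (adjusted p = 2.99e-07, and adjusted p = 0.109 with an estimated correlation), with Tnip3 at -2.76 and Tnfaip2 at -2.69. In pattern recognition 15 of 22 fell and 4 rose (median -0.54, adjusted p = 3.76e-03, and adjusted p = 0.337 with an estimated correlation). Nlrp3 (-2.51) and Clec7a (-2.84) fell, while the 4 that rose included Tlr7 (1.37) and Tlr9 (0.62), the nucleic acid sensors of pDCs. DC transcription factors fell, 19 of 26 against 4 that rose (adjusted p = 1.38e-04, and adjusted p = 0.188 with an estimated correlation), with Etv6 at -0.85 and Runx3 at 0.94. Cytoskeleton and migration genes fell, 12 of 17 against 4 that rose (adjusted p = 8.56e-04, and adjusted p = 0.188 with an estimated correlation), with Adam8 at -2.10 (62.8% of its window counts shared with neighbouring genes). Immunoregulatory genes fell, 12 of 20 against 4 that rose (adjusted p = 0.0318, and adjusted p = 0.265 with an estimated correlation), with Havcr2 at -2.30 and Cd274 at -1.20. Chemokines and their receptors fell, 7 of 15 against 3 that rose (adjusted p = 0.0420, and adjusted p = 0.282 with an estimated correlation), with Cxcl16 (95.8% of its window counts shared) at -1.05 and Ccl17 at -2.19. The immunoregulatory and chemokine lists each lost their call in 4 other settings, with medians of -0.38 to -0.17 and -0.87 to -0.38. Near gene ends the transcription factor list lost its call too (-0.26), and Cd274 changed sign (0.19).

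The remaining lists did not pass in pDC-like cells. MHC class II had 1 higher and 8 lower of 13 (adjusted p = 0.143), MHC class I 2 higher and 6 lower of 16 (0.274), and interferon-stimulated genes 8 higher and 5 lower of 20 (0.829), with Ifi44 at 2.64 and Irf7 (50.2% of its window counts shared) at 0.63. The MHC class II list passed near gene ends (median -0.21), and the glycolysis list with all myeloid clusters in the reference (-0.14). Glycolysis had 4 higher and 11 lower of 26 (adjusted p = 0.156), with Hk2 at -1.37 and Ldhb at 2.12, and fatty acid synthesis 5 higher and 4 lower of 13 (0.379), with Fads2 at 1.48 and Scd1 at -1.80. Sterol efflux had 6 higher and 3 lower of 12, and cell cycle 2 higher and 4 lower of 16 (adjusted p = 0.871). The counts adjusted over the list alone were the same in this class. The largest rises were Ppic (46.7 CPM against 0.074, with 4 counts in the others), Defb28 (74.5 against 0.438) and Gm14137 (33.8 against 0.456, log2 6.48, with 5.35 and 5.53 by library), and then Ntsr1, Tenm3 (143 against 2.01, log2 6.37), Grm7, Rtl1 and Nat3. The 8 largest falls had 0 counts. Among them 3425401B19Rik was at least 8.36-fold lower, Sncg at least 7.91-fold, and Gm14092, Grid1, Olfr738, Vmn2r82, Slc39a12 and Sel1l2 at least 3.37-fold to 5.91-fold. Gm14137 and Gm14092 shared 100% of their window counts with neighbouring genes. Gm14092 and Vmn2r82 lost their calls with all myeloid clusters in the reference, and 3425401B19Rik near gene ends (-5.45).

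Of the 60 pairs of list and class, camera with its preset correlation called 23, 3 in cDC1-like, 5 in cDC2-like, 8 in mature DC-like and 7 in pDC-like cells. None was called with an estimated correlation, where the smallest adjusted p was 0.0736. fry, which tests whether the genes of a list move on balance in 1 direction, called 51, and its mixed test of change in either direction called 15 of 15 lists in each class. Neither test compares a list with other genes. The median, the mean and camera's direction differed in sign for fatty acid synthesis, glycolysis, costimulation, chemokines and interferon-stimulated genes in cDC1-like cells. They also differed for sterol synthesis, costimulation, chemokines and cytoskeleton in cDC2-like cells and for sterol synthesis and cell cycle in pDC-like cells, none of which was called.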

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

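The shares and counts in this paragraph were flagged because they lay in cells or regions outside the comparisons of DC-like classes, above the limit that a count of 0 allows. The sterol list and the mature clusters below belong to those comparisons and were picked out on reading the tables. Of the tests below, that of class II genes in lymphocyte-like cells and that of matched lists had their predictions written before their values were seen, although clusters were recomputed later, and the other 4 were written after. T cell-like, B cell-like and NK/ILC-like cells together made up 9.12% (exact 95% interval 8.02 to 10.3) of library 1 and 8.97% (7.88 to 10.2) of library 2. Monocyte/macrophage-like cells made up 8.24% and 7.93%. Unnamed clusters held 28.8% and 27.5% of cells. Peaks on unplaced scaffolds held 87530 and 77657 counts.

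Lymphocyte-like cells stood out because the sort removed cells with lineage markers. If they were droplets with the nuclei of a lymphocyte and a DC, their counts per cell would at least match those of DC-like cells. Their median was 66.9% of the DC-like median in library 2 and 65.4% in library 1, which argues against this. Pairs sorted together whose nuclei came apart afterwards cannot be seen in counts per nucleus, so the test does not bear on them. If they were single lymphocytes that passed the sort, class II genes would be far less accessible in T cell-like and NK/ILC-like cells, and the list's median log2 fold change was -1.05 or lower in both libraries (limit set at -1). By library it was -1.33 and -2.07 in T cell-like cells and -1.29 and -1.05 in NK/ILC-like cells. An equal mixture with a DC would give about -1 for genes closed in lymphocytes, so values near the limit do not separate single cells from mixtures. Lymphocytes may have escaped the gate. B cell-like cells had 0.35 and 0.24, but the prediction was made for T cell-like and NK/ILC-like cells only, so these values do not bear on it. No biological explanation was tested, since the series has 1 group.

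The sterol synthesis list in mature DC-like cells stood out because 12 genes rose and 3 fell although the list did not pass camera. Matched on accessibility level and gene-end share, 10000 random lists gave medians from -0.09 to 0.12 (95%), and the list's 0.16 lay at percentile 99.6. The list was picked for its rises, and random draws ignore the correlation between its genes (estimated at 0.053). The percentile therefore describes the list against such draws and does not test it. If more counts near gene ends were the whole cause, the median would drop to 0 or below with those counts only, and it was 0.092 (0.12 and 0.13 per library). It did fall from 0.16, so a part due to gene ends is not excluded. A rise of sterol genes in mature DC-like cells may be worth following up, but the list's median falls to 0.03 with all myeloid clusters in the fit. In cDC1-like cells the list lies at the opposite end, at percentile 0.77, which is not an independent result since the contrasts of a gene sum to 0.

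Among 3 mature DC-like clusters, the one with 24 and 23 cells was chosen because, of the smaller ones, it had the highest mean fold of cDC1 markers (7 of 10 raised, mean 0.77). It also carried Langerhans cell markers (4 of 6, mean 0.68). Between it and the largest mature cluster, 116 genes were called that also differed 2-fold between cDC1-like and cDC2-like cells. Of these, 115 (99.1%) differed in the same direction, where independent lists would give 24.4. Choosing the cluster by its cDC1 markers and the genes by both calls favours such agreement, so 24.4 is not a fair expectation and the share is no test. Without selecting on both calls the relation across genes was weaker, with a Pearson correlation of 0.37 over the 725 genes that differed 2-fold (slope 0.35) and 0.21 over all genes. A hypothesis formed on the same data, with no group to test it against, is that mature cells may keep features of cDC1-like or cDC2-like cells. A cluster made wholly of an equal mixture or doublets with cDC1-like cells would lower genes of maturity to a median of 0.95. They stood at 1.38 against 1.52 in the largest mature cluster, which argues against such a cluster. A smaller share of doublets is not excluded, because it would lower the median by less. The genes were also picked as raised in the largest cluster, which favours its 1.52.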

How the results depend on the processing

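A minimum of 10000 counts per cell, the largest mature cluster alone, all myeloid clusters in the fit and the randomized decomposition were chosen after seeing the data, and the other settings before. Of 4100 comparisons of a named gene with another setting, 3990 counted as the same (77 lost a call, 16 gained it, 17 reversed). For list medians 1098 of 1200 did (58 lost, 43 gained, 1 reversed). A comparison counted as the same when call and direction held, and also when neither setting called it, whatever the sign. With a library left out there was no call, and as scored the comparison could only count as the same or, for a called result, as reversed. Such comparisons raise the numbers that stayed the same. Numbers of changed genes stayed within 1.5 times in 61 of 68 comparisons, numbers of changed regions in 20 of 20, and shares of cells within their intervals in 100 of 112. The cause was not tested for the changes below, unless said.

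With counts near gene ends only, which are fewer, 2550 genes changed in cDC1-like, 1624 in cDC2-like and 2149 in mature DC-like cells, and 5 lists passed in the last. With cells thinned to 5000 counts, 2343, 1343, 1822 and (pDC-like) 2456 genes changed, fewer because counts are fewer, and 5 lists passed in cDC1-like cells. With all myeloid clusters in the fit, 3 lists passed in cDC2-like cells, and the sterol list in cDC1-like cells passed (-0.21, adjusted p = 0.0172, range over alternatives 8.79e-03 to 0.469). With an estimated correlation 0 lists passed in each class. fry called 12, 12, 14 and 13 lists, among them the sterol list in cDC1-like (-0.16, adjusted p = 8.79e-03) and mature DC-like cells (0.16, adjusted p = 9.16e-03, range over alternatives 9.16e-03 to 0.870). Without the replicate block (the library term) 24 lists were called, 23 of them the same. The randomized decomposition called 20.

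Reversed near gene ends were, in cDC1-like cells, Slc2a3 (0.29), E2f2 (0.10), Srebf2 (-0.052), Hmgcr (-0.079) and Aldh1a2 (-0.87). In cDC2-like cells these were Elovl5 (-0.02) and Cd274 (-0.18), in pDC-like cells Elovl6 (-0.15), Cd274 (0.19) and Aldh1a2 (0.48). In mature DC-like cells these were Npc1 (0.18), Pfkfb3 (-0.10), Mcm5 (0.29) and the transcription factor list (median 0.066, camera direction down). With all myeloid clusters Cd200 in cDC1-like (0.42) and Insig1 in mature DC-like cells (-0.038) reversed, and Insig1 in cDC2-like cells did so at Leiden resolution 1.2 (0.14) and without centring (0.16).

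The cDC2-like share was 24.1% and 24.2% at resolution 1.2, 24.99% and 24.64% with clustering on even-numbered autosomes, and 26.0% and 26.0% without centring. In these settings a cluster with Emilin2, Nlrp3 and Cd33 among its leading genes passed the naming rule as cDC2-like. The largest unnamed cluster of the main setting had the same genes among its leading ones. The mature DC-like share was 9.32% and 9.58% on even-numbered autosomes, 9.05% and 9.30% without doublet removal, and 9.20% and 9.14% with the randomized decomposition. There a shallow cluster (0.236, 0.23 and 0.248 of the library median depth) took the mature name, with 5 of 12 markers raised. At the main setting the shallow cluster, likewise with Cacnb3 and Fgf12 among its leading genes, had 4 of 12 and stayed unnamed. With a library left out there are values and no test, and counts of calls have none. The motif result and its Fisher alternative were not run.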

Other observations

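Monocyte/macrophage-like cells and the larger unnamed clusters were fitted together with the 4 DC-like classes after the data were examined, each against the mean of the other 7 (edgeR, n = 2 libraries per cluster). In monocyte/macrophage-like cells 1683 genes rose and 1796 fell. Pattern recognition genes rose, 15 of 22 with none lower (median 0.61, adjusted p = 4.93e-09, and adjusted p = 0.0484 with an estimated correlation), as did sterol efflux and storage, 7 of 12 with 1 lower (0.22, adjusted p = 1.88e-03, and adjusted p = 0.0496 with an estimated correlation). F7 (5.50) and F10 (5.48), both of the coagulation cascade, had the largest rises, and Tnfaip6 (3.45) and Clec4e (3.27) also rose. The unnamed cluster of 297 and 283 cells had 957 genes higher and 751 lower. Its pattern recognition list (11 higher and 2 lower of 22, median 0.32), NF-kB list (10 higher and 0 lower of 20) and MHC class II list (9 higher and 0 lower of 13, median 0.25, adjusted p = 3.93e-05) rose, with adjusted p from 0.0484 to 0.0496 with an estimated correlation.

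In the unnamed cluster of 177 and 178 cells sterol synthesis and uptake rose, with 12 higher and 2 lower of 25 (median 0.17, adjusted p = 7.47e-03, and adjusted p = 0.0516 with an estimated correlation). Glycolysis and lactate handling also rose there (13 higher and 3 lower of 26, median 0.15, adjusted p = 0.0138, and adjusted p = 0.0564 with an estimated correlation), while immunoregulatory genes fell (2 higher and 13 lower of 20, adjusted p = 4.31e-03, and adjusted p = 0.0496 with an estimated correlation). Costimulation genes fell too (2 higher and 11 lower of 17, adjusted p = 0.0225, and adjusted p = 0.176 with an estimated correlation). F7 (2.48) and F10 (2.08) rose in it. Its cells were shallow, with medians of 24843 and 24618.5 counts, and 67.0% and 66.3% of their window counts lay near gene ends, against 56.0% and 55.9% in mature DC-like cells. The unnamed cluster of 206 and 179 cells had 920 genes higher and 799 lower, led by Rpl39l (6.32) and Kcnk1 (4.78), and its MHC class I list fell (1 higher and 9 lower of 16, adjusted p = 0.0151, and adjusted p = 0.0791 with an estimated correlation). The unnamed cluster of 39 and 47 cells, with medians of 7221 and 7850 counts, was not tested.

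The 3 mature DC-like clusters held 143 and 145, 24 and 23, and 23 and 17 cells, and each had 10 of 12 mature markers raised. The middle one had 7 of 10 cDC1 markers raised, against 1 and 2 in the others. Langerhans cell markers were raised in all 3, 5 of 6 in the smallest (mean 0.99), 4 in the middle one (0.68) and 2 in the largest (0.21), and of 10 cDC2 markers 5 were raised in the largest, 2 in the middle one and 3 in the smallest. Compared with the largest, the middle one had 290 genes higher and 191 lower of 7441. Ido1 (1.43) and Il12b (1.09) were higher in it, and Zeb2 (-1.28), Idi1 (-0.61), Stard4 (-0.69) and Stat1 (-0.52) were lower. Stat1 had -0.32 in library 1 and -0.85 in library 2. The libraries had 10 barcodes in common.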
